A study of Homo sapiens with 30 samples.

How the data were processed

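Sequencing of polyadenylated RNA was analysed for 30 libraries of the A375 melanoma line, in 10 groups of 3 defined by the sort for integrin β4, the side of the membrane and the number of rounds of migration. Per the labels, cells were stained with an anti-ITGB4 antibody and sorted against a gate from unstained cells, on either of 2 sorters, and the sorter of each sample was not given. Per the labels, the membranes had 5 µm pores and a fibronectin coat. The series also names cells grown from a single cell, which were not analysed here. The series describes 5 rounds of migration, whereas the sample titles give 4, 5 and 10, and the titles were followed.

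The values deposited by the authors were raw counts of reads per gene symbol, 1 file per library, with totals of reads that matched no gene, more than 1 gene or more than 1 place. The submitters' processing notes name STAR for alignment, HTSeq for counting, DESeq and the genome build hg19. Their versions and parameters, the strand setting and the gene annotation were not given in the sources used here. The files listed 26364 genes, of which 4210 had 0 counts in every library. Gene counts per library were 14258919 to 29134945. Between 22.1 and 31.8% of reads were assigned to no gene, 7.80 to 13.3% for matching more than 1 place. The files held none of the mitochondrially encoded genes. No pair of libraries in a group was a copy of the other: the chi-square per degree of freedom was at least 12.4 and log correlations ran from 0.917 to 0.991.

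Genes were kept by the edgeR filter (minimum count 10, minimum total 15), which left 15381. Counts were scaled with TMM factors and fitted with edgeR 4.0.16 (quasi-likelihood, all 10 groups in 1 fit, R 4.3.3), and 13 comparisons of groups and 3 interactions were tested, each with Benjamini-Hochberg adjustment over all genes at 0.05. The SE of a log2 fold change is its size divided by the square root of F. Log levels used a prior count of 2. Rose, fell, higher and lower for single genes refer to genes past this threshold unless a p is given. The named genes were ITGB4 and the genes with the highest and the lowest log2 fold change among those called, at a mean of at least 5 CPM in 1 group and with no overlap of the 3 and 3 libraries, 8 each way in the 5 main comparisons and 4 each way in the others. They also took in up to 4 called members of each list with the smallest p. Chance alone separates 3 from 3 libraries without overlap in 10% of genes. For single values compared 3 against 3, the smallest exact permutation p is 0.1, so levels were compared through the model.

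Sets of genes were tested with camera (limma 3.58.1), with a preset correlation of 0.01 and again with an estimated correlation, on 35 lists of adhesion, matrix, pigment cell state, cell cycle, signalling, stress, immune and cell type marker genes. A list was run with at least 5 tested members, which left out the mitochondrially encoded genes. Adjustment was over the lists of a comparison. Calls shared by comparisons with no library in common were counted and tested with Fisher's exact test, one-sided, which takes genes as independent. Genes were assigned to chromosomes by symbol in a RefSeq annotation of GRCh38, 98.1% of those tested (14139 by symbol and 945 by an older symbol). No coordinates are given because the counts were made on another build. The median log2 fold change of each chromosome, less that of all genes, was set against 10000 random gene sets matched in 20 bins of expression. Transcript length and GC content came from a GENCODE annotation (Biostrings 2.70.1) for 97.25% of tested genes.

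The fit was tested on simulated data of 1 comparison of 3 against 3. It called 30 of 100 genes changed 2-fold and 83 of 100 changed 4-fold, 0 in the wrong direction, with 3 false among 116 calls. The camera test called the list that had been raised. Of 200 random lists it called 6 without adjustment. Genes were simulated independently of each other, so this does not test the preset correlation for the real data. Most 2-fold changes were thus missed at this number of libraries.

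The comparisons, gene lists, tests and named gene rule were chosen before the data were examined, and so were these alternatives: DESeq2 1.42.0, RLE scaling factors, no filter on low counts, a replicate block, only the compared groups in the fit, leaving out each library in turn and the estimated correlation. Chosen after seeing the data were a replicate block in the groups whose replicate numbers pair and a fit without 6 libraries that stood apart on the second principal component (score above 30). A pairing was taken where libraries of 2 groups with the same replicate number correlated above 0.1 for each of the 3 numbers, after group means were removed. The labels do not state a pairing. The chromosome analysis and the score of shared genes were chosen after the comparisons had been seen. Ratios with few counts carry a 95% counting interval. The first 3 principal components held 32.4, 21.2 and 12.1% of the variance.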

Results

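Polyadenylated RNA of A375 cells, an established human melanoma line, was sequenced in 30 libraries, 3 in each of 10 groups. Cells had been sorted by surface integrin β4 (ITGB4, the laminin receptor subunit that anchors hemidesmosomes) and taken through transwell membranes with 5 µm pores. Parental negative and Parental positive cells went through 0 rounds. Top 10 cells failed to cross in 10 rounds and Bottom 10 cells crossed in 10 rounds, each as a negative and a positive sort. Top 5 positive cells failed to cross in 5 rounds and Bottom 5 negative cells crossed in 5. The last pair of groups was sorted from parental cells and then migrated, the negative sort for 4 rounds and the positive sort for 5. The series title sets differences that exist before migration beside those that arise with it, and the sort and the migration comparisons address these in turn. Counts assigned to genes ran from 14258919 to 29134945 per library. In each library 17310 to 18288 genes had at least 1 count. Of 26364 listed genes, identified by symbol, 15381 had enough counts to be tested. Levels below are counts-per-million (CPM) with the SD over n = 3 libraries, and log2 fold changes carry the SE of the fit. The labels number the libraries of a group as biological replicates without saying whether they came from separate cultures, so p-values measure the spread between these samples.

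ITGB4 transcript was higher in the positive than in the negative sort of all 3 populations, but none of the differences passed the test over all genes. Its level was 27.8 ± 5.13 CPM in Parental negative and 100.1 ± 66.6 in Parental positive cells, a log2 fold change of 1.85 ± 0.87 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1). Top 10 cells held 7.38 ± 5.17 CPM in the negative and 28.9 ± 24.5 in the positive sort, a log2 fold change of 1.97 (edgeR adjusted p = 1). Bottom 10 cells held 49.0 ± 33.9 and 130.0 ± 113 CPM, a log2 fold change of 1.41 (edgeR adjusted p = 1). Between Bottom 10 and Top 10 cells the log2 fold change was 2.73 ± 0.91 in the negative sort (edgeR adjusted p = 0.187) and 2.17 ± 0.88 in the positive sort (edgeR adjusted p = 0.378). The mean was 135 ± 162 CPM in the negative sort after 4 rounds, where 1 library held 322 CPM, and 194 ± 149 in the positive sort after 5. It was 86.3 ± 61.2 CPM in Bottom 5 negative and 28.2 ± 14.9 in Top 5 positive cells. Against parental cells of the same sort the log2 fold change was -1.91 ± 0.88 in Top 10 negative and -1.79 ± 0.87 in Top 10 positive cells. It was 0.82 ± 0.85 in Bottom 10 negative and 0.38 ± 0.84 in Bottom 10 positive cells, and none of the 4 passed (edgeR adjusted p of 0.55 or more).

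Libraries of the Top 10 and Bottom 10 groups that carried the same replicate number resembled each other, except replicate 1 of Top 10 negative and Bottom 10 positive cells (correlation -0.122 after group means were removed), so a fit with replicate number as a term, restricted to these 4 groups, was added after seeing the data. The p-values of that fit do not allow for the choice of the term from these same data. In that fit ITGB4 was higher in 3 of 3 pairs in each comparison. The log2 fold change between the sorts was 1.86 ± 0.22 in Top 10 cells (edgeR adjusted p = 0.0143) and 1.22 ± 0.21 in Bottom 10 cells (edgeR adjusted p = 0.0345). Between Bottom 10 and Top 10 cells it was 2.76 ± 0.23 in the negative sort (edgeR adjusted p = 9.15e-05) and 2.12 ± 0.21 in the positive sort (edgeR adjusted p = 0.00037). Without replicate 2 of every group these adjusted p-values were 0.886, 0.803, 0.0298 and 0.0571, in the same order, and without replicate 1 they were 0.236, 0.169, 0.00351 and 0.00843.

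**Figure D1:**
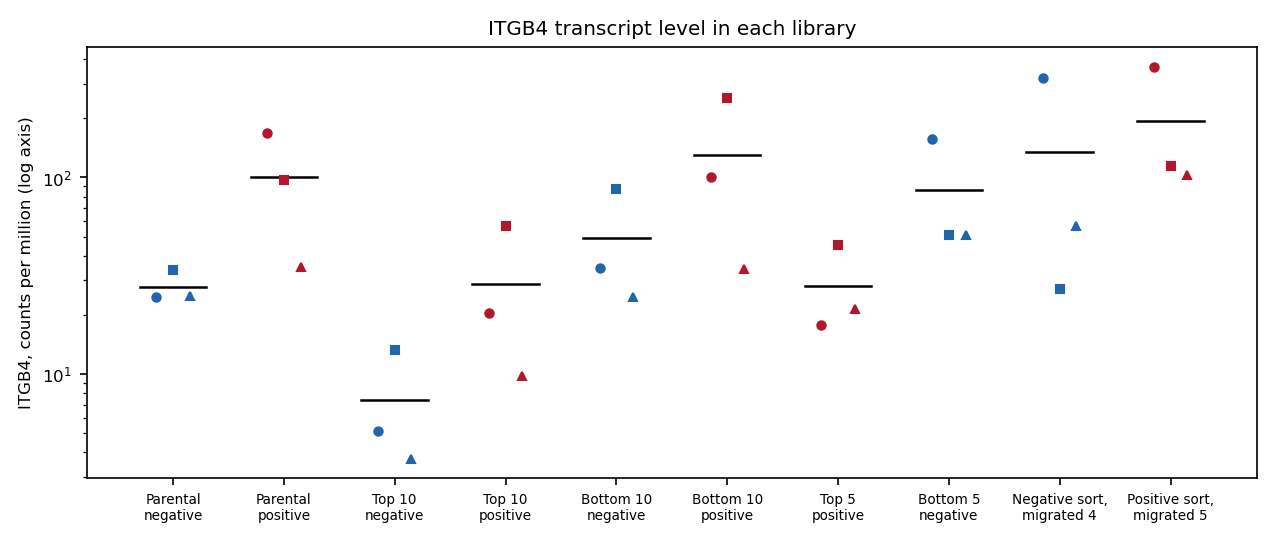
ITGB4 level in CPM (log axis) in each of the 30 libraries, by group; blue is the negative and red the positive sort, circles, squares and triangles are replicates 1, 2 and 3, and bars are group means. Group means run from 7.38 in Top 10 negative to 194 in the positive sort migrated 5 rounds.

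In parental cells, few single genes separated the sorts. FOXP1, a forkhead transcription factor, rose from 4.54 ± 1.15 CPM in negative to 19.2 ± 2.96 CPM in positive cells (log2 fold change 2.08 ± 0.32, edgeR adjusted p = 0.00333). FBXL7, the substrate-binding part of a ubiquitin ligase, rose from 5.15 ± 0.85 to 20.7 ± 5.84 CPM (edgeR adjusted p = 0.00184). ZFPM2, a cofactor of GATA factors, rose from 8.07 ± 0.90 to 25.7 ± 3.05 CPM (edgeR adjusted p = 0.00184). PGM5, a protein of cell-matrix and cell-cell junctions, rose 6.54-fold (edgeR adjusted p = 0.0357), and ANKRD30A, known as a breast differentiation antigen, 3.94-fold (edgeR adjusted p = 0.0189). EYA1, a transcriptional coactivator and phosphatase of organ development, fell from 39.4 ± 13.0 to 9.27 ± 2.90 CPM (edgeR adjusted p = 0.00184). SOX11, a factor of neural development, fell from 114 ± 25.8 to 36.3 ± 14.4 CPM (edgeR adjusted p = 0.0189). In all, edgeR called 9 genes, 6 higher and 3 lower in the positive sort. FBXL7, ZFPM2 and EYA1 kept an adjusted p under 0.05 whichever library was left out. FOXP1 lost it without Parental negative replicate 2 (0.0854), PGM5 in all but 1 of the 6 fits (up to 0.291, kept without Parental positive replicate 3), and ANKRD30A and SOX11 without replicates 1 and 2 of either group (up to 0.163 and 0.226). The count was 4 and 3 without Parental negative replicates 1 and 2, and 4, 4 and 18 without Parental positive replicates 1, 2 and 3. It was 1 with only these 2 groups in the fit, 27 with a replicate block, 25 without 6 libraries that stood apart from the rest, and 75 with DESeq2.

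Gene lists were also compared between the parental sorts. Of 52 measured G2/M genes 51 were higher in the positive sort (median log2 fold change 0.39, adjusted p = 8.43e-16), and of 43 S-phase genes 43 were (median 0.37, adjusted p = 3.4e-09). Of 31 genes of the dedifferentiated melanoma state 27 were higher (adjusted p = 1.93e-07), with 18 of 24 targets of YAP and TEAD (adjusted p = 0.00481) and 8 of 10 hemidesmosome genes (adjusted p = 0.0274). Unfolded protein genes (4 of 26 higher, adjusted p = 0.0274) and antigen presentation genes (7 of 21 higher, adjusted p = 0.0248) went down as lists. Another 7 lists were called, cohesin and condensin, actomyosin, nuclear envelope and cancer-testis genes higher and mesenchymal factors, melanocyte lineage and neural genes lower (adjusted p from 0.000471 to 0.0481). No member of these 14 lists passed the edgeR test over all genes, and adjusted over the list alone 1 actomyosin gene and 2 mesenchymal factors did. All these list calls were from camera with a preset correlation of 0.01, and none held with an estimated correlation, where adjusted p ran from 0.479 to 0.669. Parental negative replicate 1 had the lowest mean of the G2/M list among the 6 parental libraries.

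The sort gave few calls after 10 rounds. In Top 10 cells PKP2, a desmosomal plaque protein, rose from 1.25 ± 0.33 CPM in negative to 5.69 ± 0.84 CPM in positive cells (log2 fold change 2.19 ± 0.38, edgeR adjusted p = 0.0424), 1 of 2 genes called. In Bottom 10 cells 0 genes were called by edgeR and 5 by DESeq2. At an unadjusted edgeR p under 0.05 there were 549, fewer than the 769 expected by chance. This fit had no term for replicate number, so a count below chance does not show that the sorts were alike. As lists, YAP and TEAD targets were higher in Top 10 positive cells (22 of 24 genes, camera adjusted p = 6.83e-07), as were dedifferentiated genes (25 of 31, adjusted p = 2.19e-05). Keratinocyte markers were higher in Bottom 10 positive cells (11 of 12, adjusted p = 0.00209), and fibroblast markers lower (6 of 8, adjusted p = 0.0308). Adjusted p with an estimated correlation was 0.256, 0.388, 0.139 and 0.139 for these 4 lists. Adjusted over the list alone, 0 of their members were called. PKP2 lost the call in each of 6 leave-one-out fits (adjusted p up to 0.699). The Top 10 count of 2 was 1 without Top 10 negative replicate 2 and 0 without any of the other 5 libraries, and the Bottom 10 count was 1 without Bottom 10 positive replicate 1. With the replicate block in the 4 groups, the edgeR counts were 35 and 121 genes, and neither held without 1 replicate number. They were 0 and 6 without replicate 1, 0 and 0 without replicate 2, and 55 and 35 without replicate 3. At an unadjusted p under 0.05 the full paired fit had 1049 and 2066 of 14587 genes. There were 544 and 2561 without replicate 1, 437 and 687 without replicate 2, and 1827 and 1666 without replicate 3. DESeq2 was not run with this block. The sort differences in Bottom 10 and parental cells were compared as an interaction, which called 0 genes in edgeR and 2 in DESeq2. At an unadjusted edgeR p under 0.05 it had 463, where chance gives 769.

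Negative cells that crossed in 10 rounds differed from those that did not in 205 genes called by edgeR, 146 higher and 59 lower in Bottom 10 cells. MME, the membrane peptidase neprilysin, rose from 0.16 ± 0.13 CPM in Top 10 to 5.99 ± 3.03 CPM in Bottom 10 cells (edgeR adjusted p = 0.000653). PDGFB, a platelet-derived growth factor chain, rose from 0.23 ± 0.05 to 8.56 ± 4.28 CPM (edgeR adjusted p = 2.78e-05). ESM1, the proteoglycan endocan, rose from 0.41 ± 0.44 to 14.5 ± 5.96 CPM (edgeR adjusted p = 0.00128). TMPRSS15, the protease enteropeptidase, rose from 2.06 ± 0.54 to 42.9 ± 17.3 CPM (edgeR adjusted p = 1.31e-05). SERPINB7, PLXDC2, TM4SF18 and UCA1 rose 26.1-, 20.4-, 19.5- and 17.1-fold. SOX8, a factor of the neural crest, fell from 8.03 ± 5.84 to 0.11 ± 0.11 CPM (edgeR adjusted p = 0.00448). TRIM51, GRM8 and TESC fell with log2 fold changes of -4.44, -4.20 and -3.58. LAD1, a basement membrane anchoring protein, fell from 23.3 ± 7.62 to 2.50 ± 0.30 CPM (edgeR adjusted p = 0.00335). SCARA5, a ferritin receptor, fell from 33.5 ± 3.98 to 4.27 ± 1.93 CPM (edgeR adjusted p = 0.0017). SORCS1 and EWSAT1 fell by 2.62 and 2.41 on the log2 scale. Of 37 named genes 15 kept the call whichever library was left out, among them MME, ESM1, PDGFB, TMPRSS15, SOX8, TRIM51, LAD1 and SCARA5. SERPINB7 and TM4SF18 lost it without Top 10 negative replicate 1 or 2, TESC without Bottom 10 negative replicate 2 or 3, and UCA1, GRM8 and SORCS1 in 4 or 5 of 6 fits (adjusted p up to 0.268). The count was 96, 107, 147 and 91 without Top 10 negative replicates 1 and 2 and Bottom 10 negative replicates 1 and 2 (157 and 152 without replicate 3). It was 383 with DESeq2 and 1355 (686 higher, 669 lower) with the replicate block in the 4 groups, where it fell to 515 and 116 without replicates 1 and 2.

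Dedifferentiated melanoma genes were the list with the smallest p in that comparison, with 28 of 31 higher in Bottom 10 negative cells (median log2 fold change 0.76, camera adjusted p = 1.32e-11, adjusted p = 0.154 with an estimated correlation). Among them 4 rose over all genes and 14 adjusted over the list alone. The 4 were NRG1, a ligand of ERBB receptors (12.2-fold), SOX9, a neural crest factor (9.11-fold), the AP-1 subunit JUN (3.04-fold) and the adaptor AJUBA (4.04-fold). Of 24 targets of YAP and TEAD 21 were higher (camera adjusted p = 1.21e-07, adjusted p = 0.196 with an estimated correlation), with 2 called over all genes and 9 adjusted over the list alone. Matrix collagens rose in 3 cases, COL13A1 (5.35-fold), COL12A1 (4.71-fold) and COL5A2 (2.26-fold, from 167 ± 26.8 to 377 ± 45.6 CPM), and LAMA1, a laminin chain, rose 10.1-fold (edgeR adjusted p = 0.000706). POSTN, the matrix protein periostin, rose from 0.10 ± 0.09 to 1.2 ± 0.59 CPM, with the collagens the 4 called genes of the interstitial matrix list. That list went both ways in the fit with the replicate block, where 7 of 31 genes rose and 7 fell, COL6A2, COL9A3, THBS2, FBLN1, FBLN5, ELN and EMILIN1. Inflammatory genes IL1B (19.4-fold), CCL2 (13.7-fold) and CXCL8 (5.48-fold) rose, 3 of 24 in the NF-κB list and 4 adjusted over the list alone (camera adjusted p = 0.00568, adjusted p = 0.442 with an estimated correlation). L1CAM, a neural adhesion molecule, rose 6.06-fold, the endothelial marker TIE1 7.64-fold, and ADAMTS1, NUAK2, PLK2 and ASTN1 rose 2.40-, 3.41-, 2.94- and 6.86-fold. EPHB3, an ephrin receptor, fell from 28.7 ± 2.48 to 11.8 ± 1.65 CPM (edgeR adjusted p = 0.0061). Of 52 G2/M genes 51 were higher (camera adjusted p = 1.21e-07, adjusted p = 0.586 with an estimated correlation), and adjusted over the list alone 0 were called. Of the called genes named here NRG1, COL13A1, LAMA1, IL1B and ASTN1 kept the call whichever library was left out. EPHB3 lost it without Bottom 10 negative replicate 2, CCL2 without Top 10 negative replicate 1 or 2 and ADAMTS1 without replicate 1 of either group. SOX9, JUN, AJUBA, COL12A1, COL5A2, POSTN, CXCL8, L1CAM, TIE1, NUAK2 and PLK2 each lost it without Top 10 negative replicate 1 and without Bottom 10 negative replicate 2, and in 3 to 5 of 6 fits in all (adjusted p up to 0.3).

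In the positive sort, PGM5 rose from 0.30 ± 0.05 CPM in Top 10 to 12.7 ± 4.97 CPM in Bottom 10 cells (edgeR adjusted p = 3.04e-05). TMPRSS15 rose from 3.21 ± 1.18 to 61.5 ± 27.5 CPM (edgeR adjusted p = 3.39e-05), and PTPRD, a receptor tyrosine phosphatase, from 0.91 ± 0.11 to 13.5 ± 7.25 CPM (edgeR adjusted p = 5.62e-05). ASTN1, a neuronal migration protein, rose 14.5-fold, S1PR1, the receptor for sphingosine 1-phosphate, 10.97-fold, and IL1B 12.9-fold. EYA1 fell from 40.5 ± 11.5 to 7.11 ± 2.54 CPM (edgeR adjusted p = 5.62e-05). SORCS1, a neuronal sorting receptor, fell from 50.5 ± 12.5 to 4.13 ± 2.48 CPM (edgeR adjusted p = 0.00466), and FREM1, an extracellular matrix protein, from 8.46 ± 3.39 to 0.60 ± 0.44 CPM (edgeR adjusted p = 0.00584). PCDH7, SCARA5, LRP3 and ZNF208 fell with log2 fold changes of -2.79, -2.51, -2.36 and -2.15. In all, edgeR called 145 genes, 97 higher and 48 lower. Of 25 named genes 13 kept the call whichever library was left out, among them PGM5, TMPRSS15, PTPRD, ASTN1, S1PR1, EYA1, SORCS1 and FREM1. IL1B lost it without Top 10 positive replicate 1 or 3 or Bottom 10 positive replicate 2, and SCARA5 without Top 10 positive replicate 1 or Bottom 10 positive replicate 2 or 3 (adjusted p up to 0.116). The count was 53, 75 and 63 without Top 10 positive replicates 1, 2 and 3 and 64 and 79 without Bottom 10 positive replicates 2 and 3. It was 31 with only these 2 groups in the fit, 280 with DESeq2 and 1130 (573 higher, 557 lower) with the replicate block in the 4 groups, where it fell to 643 and 92 without replicates 1 and 2.

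Of the lists in the positive sort, dedifferentiated genes were higher in 25 of 31 (median log2 fold change 1.00, camera adjusted p = 2.81e-07, adjusted p = 0.333 with an estimated correlation), with TNFRSF12A, a receptor of the tumour necrosis factor family, called over all genes (2.03-fold) and 12 genes adjusted over the list alone. NF-κB genes were higher in 18 of 24 (camera adjusted p = 4.93e-06, adjusted p = 0.269 with an estimated correlation), with IL1B and CCL2 (12.6-fold) called and 5 adjusted over the list alone. This list also passed in the fit with the replicate block (adjusted p = 0.0323 with an estimated correlation). KRT81, LAMA1, COL13A1 and GADD45B rose 13.6-, 5.35-, 4.86- and 2.43-fold, and EPHB3 and SEMA6A fell with log2 fold changes of -1.10 and -1.35. Leaving out 1 library ended the calls of EPHB3 and SEMA6A in 6 of 6 fits (adjusted p up to 0.23) and those of TNFRSF12A and GADD45B in all but the fit without Bottom 10 positive replicate 1 (up to 0.291). CCL2 and LAMA1 lost theirs in 3 fits each (up to 0.142) and KRT81 without Top 10 positive replicate 3 (0.0512), whereas COL13A1 kept it in all 6. VCX2, GAGE2A, CTAG2 and KRT81 have near-identical copies in the genome, so their counts are uncertain. The migration differences of the sorts shared 59 higher and 18 lower genes, where 0.921 and 0.184 would be expected of independent comparisons, and 0 genes called in opposite directions. With the replicate block in the 4 groups, 328 higher and 305 lower genes were shared and 3 went opposite ways. Libraries of the sorts with the same replicate number resembled each other, so the comparisons were not independent. Their difference, tested as an interaction, called 0 genes in edgeR, with 441 at an unadjusted p under 0.05 (769 expected by chance) and 0 in DESeq2. With the replicate block in the 4 groups the interaction also called 0 genes in edgeR, with 1905 at an unadjusted p under 0.05.

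**Figure D2:**
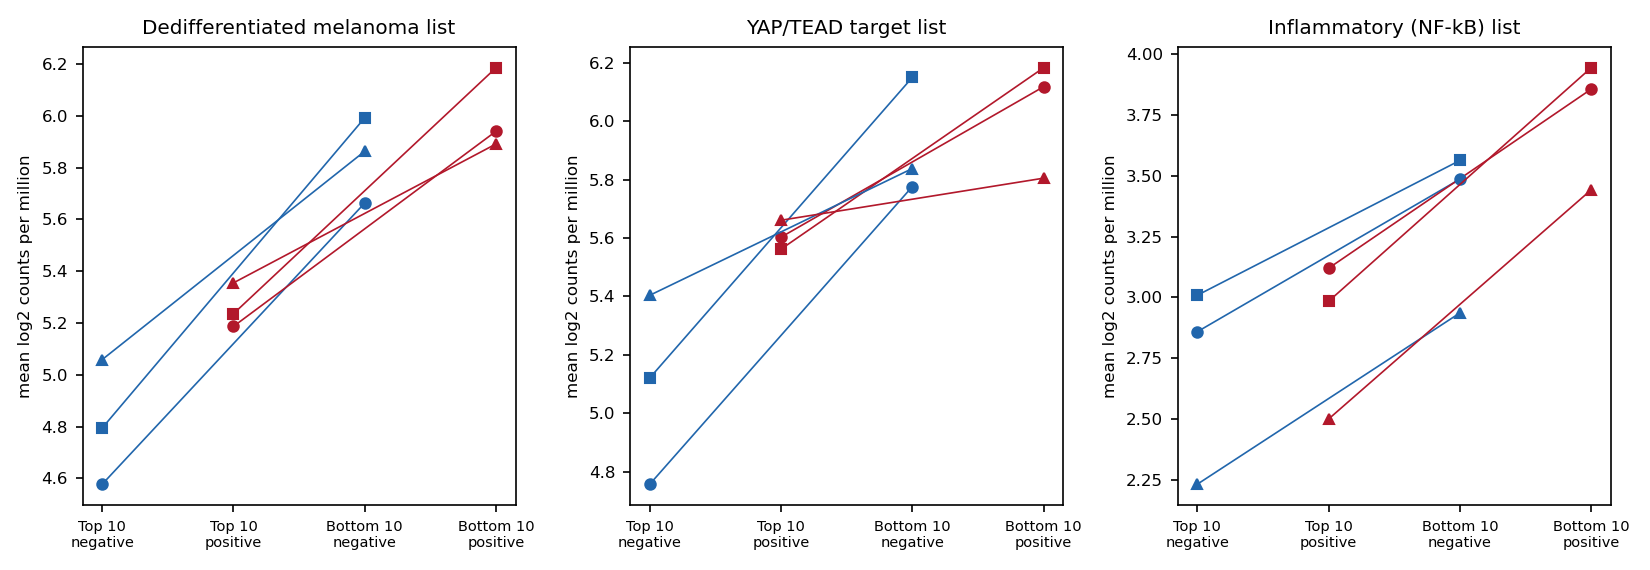
Mean level (log2 CPM) in 3 gene lists in each of the 12 libraries of 10 rounds; blue is the negative and red the positive sort, circles, squares and triangles are replicates 1, 2 and 3, and lines join libraries of 1 sort with the same replicate number. In each of the 3 lists the Bottom 10 library lies above the Top 10 library in 6 of 6 pairs.

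Of the 9 genes called between the parental sorts, 6 were also called between Bottom 10 and Top 10 cells in the same direction. FBXL7, FOXP1, PGM5 and ZFPM2 rose in the parental positive sort and in Bottom 10 cells of both sorts, and EYA1 fell in all 3 comparisons, with SOX11 lower in the parental positive sort and in Bottom 10 positive cells. The 4 higher genes compare with 0.0570 expected against the negative sort (Fisher's exact test, one-sided, adjusted p = 4.27e-07) and 0.0378 against the positive sort (adjusted p = 9.58e-08). The lower genes, 1 and 2 of 3, had adjusted p = 0.0272 and 8.26e-05. These comparisons share no library, but genes are not independent, so these p-values overstate the evidence. With PGM5 at 2 counts in all 3 Top 10 negative libraries together and 310 in Bottom 10 negative, the ratio was 141 (95% counting interval 38.8 to 1173, counting error only). The score of the 6 genes (mean log2 CPM of the higher minus that of the lower) was -3.86 ± 0.44 in Parental negative, 0.10 ± 0.56 in Parental positive, -6.23 ± 0.07 in Top 10 negative and -1.51 ± 0.455 in Bottom 10 negative, -4.64 ± 0.29 in Top 10 positive and 0.29 ± 0.66 in Bottom 10 positive cells. ANKRD30A, SLCO1B3 and TRO were called between the parental sorts but in neither of these migration comparisons (edgeR adjusted p from 0.106 to 0.999). By a RefSeq annotation of GRCh38 the genes lie on chromosomes 2 (SOX11), 3 (FOXP1), 5 (FBXL7), 8 (EYA1 and ZFPM2) and 9 (PGM5).

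**Figure D3:**
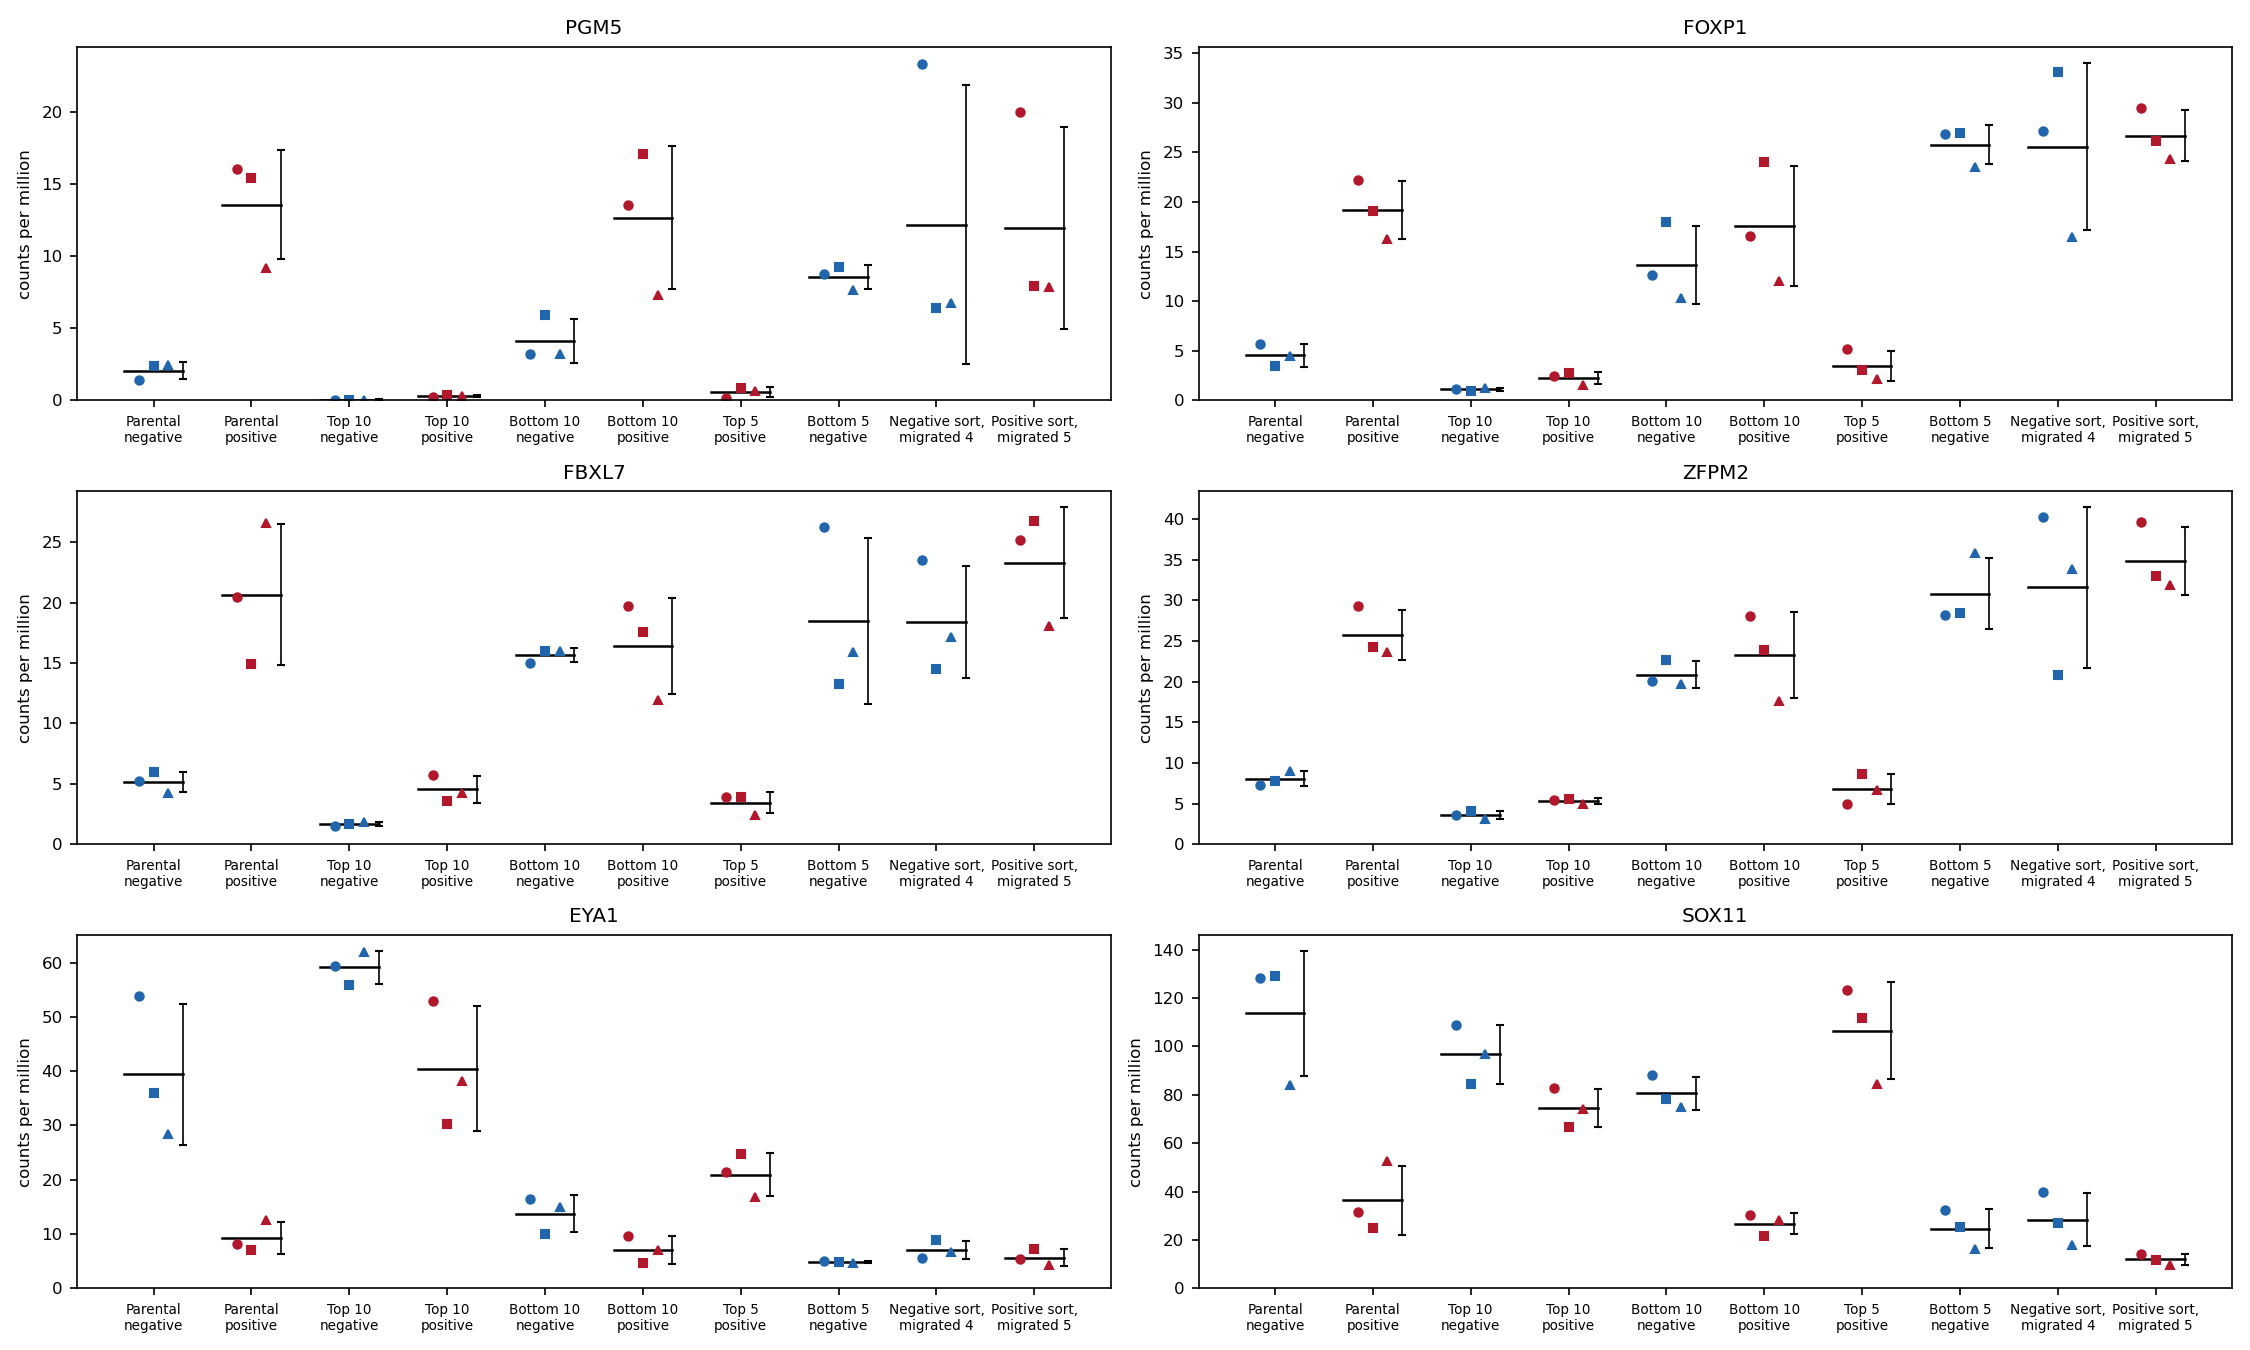
Levels in CPM (linear axes from 0) of the 6 genes called in the same direction between the parental sorts and between Bottom 10 and Top 10 cells, in each of the 30 libraries by group; blue is the negative and red the positive sort, symbols are replicates 1, 2 and 3, bars are group means and error bars SD. PGM5 was at 2 counts over the 3 Top 10 negative libraries.

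Differences from parental cells mix crossing, or failing to cross, with the rounds themselves and with any difference in processing. The share of reads assigned to no gene was 24.1 to 26.5% in parental libraries and 22.1 to 23.6% in those of 10 rounds. Against parental cells of the same sort, Bottom 10 cells had higher TMPRSS15, which rose from 3.83 ± 1.97 to 42.9 ± 17.3 CPM in the negative sort (edgeR adjusted p = 0.00254) and from 7.79 ± 0.59 to 61.5 ± 27.5 CPM in the positive sort (edgeR adjusted p = 0.0037). In the negative sort PLXDC2 rose 9.01-fold, PDGFB 5.11-fold and PXDN, a matrix peroxidase, from 10.6 ± 2.00 to 47.6 ± 2.21 CPM (edgeR adjusted p = 0.0074). SOX8, PALD1, PCSK1N, TAGLN and EPHB3 fell with log2 fold changes of -5.32, -2.13, -2.51, -1.63 and -1.27. That of SOX8 ran from -6.51 to -3.40 when single libraries were left out. In the positive sort PTPRD rose 10.8-fold (edgeR adjusted p = 0.000716), ZNF385D 5.64-fold, ASTN1 5.23-fold and MAFF, a small basic leucine zipper factor, 1.96-fold. MITF, the master regulator of melanocytes, fell from 58.0 ± 6.47 to 28.2 ± 5.30 CPM (edgeR adjusted p = 0.0243). ANKRD30A fell from 10.2 ± 1.48 to 1.30 ± 0.18 CPM (edgeR adjusted p = 0.000356), and MAGEA1 from 33.9 ± 9.43 to 8.17 ± 2.77 CPM. TNRC6C-AS1 fell in both sorts, with log2 fold changes of -2.61 and -2.72, and is uncertain since it runs antisense to another gene and the strand of counting was not given. MAGEA1 and GAGE2A (10.4-fold higher) have close copies and are uncertain too.

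EdgeR called 50 genes in the negative sort (21 higher, 29 lower) and 38 in the positive sort (20 higher, 18 lower). In the negative sort 49 of 52 G2/M genes were higher (camera adjusted p = 6.8e-12, adjusted p = 0.626 with an estimated correlation), with Parental negative replicate 1, low in G2/M genes, among the parental libraries, and 33 of 36 hypoxia and glycolysis genes (adjusted p = 1.43e-05, adjusted p = 0.501 with an estimated correlation), and adjusted over the list alone 0 were called. In the positive sort unfolded protein genes were higher in 22 of 26 (adjusted p = 3.43e-10, adjusted p = 0.301 with an estimated correlation), 0 over all genes and 15 adjusted over the list alone. Antigen presentation genes were higher in 19 of 21 (adjusted p = 5.73e-07, adjusted p = 0.379 with an estimated correlation), with 0 adjusted over the list alone, and 5 of 6 leukocyte markers were lower (adjusted p = 0.0465, adjusted p = 0.379 with an estimated correlation), with 1 adjusted over the list alone. The negative-sort count was 20 and 5 without Parental negative replicates 1 and 2, 14, 14 and 24 without the Bottom 10 negative replicates, and 39 without Parental negative replicate 3. The positive-sort count was 14, 11 and 18 without the Parental positive and 12, 11 and 16 without the Bottom 10 positive replicates. With only the compared groups in the fit each count was 0, and DESeq2 gave 169 and 113. TMPRSS15 in both sorts, and PTPRD and ANKRD30A in the positive sort, kept the call whichever library was left out, unlike the other named genes of this comparison.

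In the positive sort, PGM5 was lower in Top 10 than in parental cells and fell from 13.6 ± 3.805 to 0.30 ± 0.05 CPM (edgeR adjusted p = 1.7e-05). ANKRD30A fell from 10.2 ± 1.48 to 0.75 ± 0.44 CPM (edgeR adjusted p = 5.28e-06) and MAGEA1 from 33.9 ± 9.43 to 4.06 ± 0.36 CPM (edgeR adjusted p = 4.72e-05). COL13A1 fell by 1.87 on the log2 scale, with VCX2 and VCX lower at log2 fold changes of -3.49 and -3.34. EYA1 rose from 9.27 ± 2.90 to 40.5 ± 11.5 CPM (edgeR adjusted p = 0.000411). MFSD12, a lysosomal and melanosomal transporter, rose from 125 ± 23.0 to 379 ± 42.1 CPM (edgeR adjusted p = 0.00104). SCARA5, SLC1A1 and CTAG2 rose 5.35-, 3.32- and 5.92-fold. In the negative sort PKP2 fell from 5.65 ± 2.28 to 1.25 ± 0.33 CPM (edgeR adjusted p = 0.0236) and FBXL7 from 5.15 ± 0.85 to 1.68 ± 0.16 CPM (edgeR adjusted p = 0.0391). EdgeR called 59 genes in the positive sort (9 higher, 50 lower) and 7 in the negative sort (0 higher, 7 lower). The positive-sort count was 25, 29 and 101 without the Parental positive and 22, 20 and 33 without the Top 10 positive replicates, 13 with only the compared groups in the fit and 210 with DESeq2. The negative-sort count was 26 and 1 without Parental negative replicates 1 and 3 and 0, 0 and 1 without the Top 10 negative replicates, 0 with only the compared groups in the fit and 48 with DESeq2. EYA1, MFSD12, PGM5, ANKRD30A and MAGEA1 in the positive sort kept the call whichever library was left out, unlike the other genes named there, and neither PKP2 nor FBXL7 did in the negative sort (adjusted p up to 0.275).

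Antigen presentation genes were higher in Top 10 than in parental cells of the negative sort (20 of 21, camera adjusted p = 3.43e-07, adjusted p = 0.455 with an estimated correlation) and of the positive sort (18 of 21, adjusted p = 1.01e-06, adjusted p = 0.387 with an estimated correlation). Adjusted over the list alone, 0 and 8 of these genes were called, and 0 over all genes. Unfolded protein genes were higher in 24 of 26 (adjusted p = 0.000348, adjusted p = 0.473 with an estimated correlation) and 23 of 26 (adjusted p = 6.94e-07, adjusted p = 0.387 with an estimated correlation). In the positive sort both lists were also higher in Bottom 10 than in parental cells, so there they were not particular to cells that did not cross. Dedifferentiated genes were lower in 26 of 31 in the negative sort (adjusted p = 0.000348, adjusted p = 0.455 with an estimated correlation) and 27 of 31 in the positive sort (adjusted p = 3.49e-05, adjusted p = 0.387 with an estimated correlation), with 3 and 1 adjusted over the list alone. Intermediate filament genes were lower in 13 of 14 in the negative sort (median log2 fold change -0.97, adjusted p = 0.000348, adjusted p = 0.166 with an estimated correlation).

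After 5 rounds, Bottom 5 negative cells had higher FOXP1, which rose from 4.54 ± 1.15 CPM in Parental negative to 25.8 ± 1.95 CPM (edgeR adjusted p = 0.000254). ANKRD30A rose 4.62-fold (edgeR adjusted p = 0.00209), PTX3, a secreted pattern recognition protein, 6.499-fold, and S1PR1 4.71-fold. SORCS1 fell from 50.9 ± 30.7 to 1.60 ± 1.51 CPM (edgeR adjusted p = 0.000663). EPHB3 and SEMA6A fell by 1.38 and 1.47 on the log2 scale, and ITGA9, an integrin α subunit, fell from 31.6 ± 32.0 to 2.61 ± 1.89 CPM (edgeR adjusted p = 0.0448). SOX8 was at 2 counts over the 3 Bottom 5 negative libraries and 264 over the Parental negative ones, a ratio of 137 (95% counting interval 37.4 to 1134, counting error only). Of the 264 counts 215 came from Parental negative replicate 1, and SOX8 lost the call without it and without Bottom 5 negative replicate 2 or 3 (adjusted p up to 0.115). EdgeR called 132 genes, 41 higher and 91 lower, and 542 with replicate number as a term in these 2 groups, a fit added after seeing the data. Without replicates 1 and 2 that count was 1489 and 81. In the same fit ITGB4 was higher in 3 of 3 pairs, with a log2 fold change of 1.43 ± 0.36 (edgeR adjusted p = 0.0764). Without replicates 1, 2 and 3 this adjusted p was 0.0145, 0.145 and 4.17e-06. Such fits kept 2 libraries per group beside the replicate term, so the spread of a gene rested mostly on that of all genes. Dedifferentiated genes were higher in 24 of 31 (camera adjusted p = 4.34e-05, adjusted p = 0.442 with an estimated correlation), with CAV2, a caveolin, called (2.45-fold) and 4 adjusted over the list alone. The count was 30 and 49 without Parental negative replicates 1 and 2 and 40 and 29 without Bottom 5 negative replicates 2 and 3, with 124 and 92 without Parental negative replicate 3 and Bottom 5 negative replicate 1. It was 0 with only the compared groups in the fit and no replicate term, 76 without the 6 libraries that stood apart, and 314 with DESeq2. FOXP1, ANKRD30A and SORCS1 kept the call whichever library was left out, and the other genes named here lost it in 3 to 5 of 6 fits (adjusted p up to 0.494).

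In Top 5 positive cells, after 5 rounds without crossing, PGM5 fell from 13.6 ± 3.805 CPM in Parental positive to 0.57 ± 0.36 CPM (edgeR adjusted p = 0.000271). FBXL7 fell from 20.7 ± 5.84 to 3.43 ± 0.88 CPM (edgeR adjusted p = 9.27e-05) and FOXP1 from 19.2 ± 2.96 to 3.43 ± 1.53 CPM (edgeR adjusted p = 0.000271). LAMA1 fell by 2.40 on the log2 scale, while SOX11 rose from 36.3 ± 14.4 to 106.6 ± 20.004 CPM (edgeR adjusted p = 0.0226). BARX1 and IRX5, homeobox factors, rose 4.10- and 3.20-fold, IGFBP2 2.59-fold and TWIST1, a factor of epithelial-mesenchymal transition, 1.84-fold. EdgeR called 25 genes, 6 higher and 19 lower. Basement membrane genes were lower in 17 of 19 (camera adjusted p = 0.000172, adjusted p = 0.73 with an estimated correlation), 1 over all genes and 2 adjusted over the list alone, as were dedifferentiated genes in 28 of 31 (adjusted p = 0.000172, adjusted p = 0.73 with an estimated correlation), 0 adjusted over the list alone. Top 5 positive replicates 1 and 3 were 2 of the 6 libraries that stood apart. The deviation of these 6 from the other libraries fell with transcript length, as described below. Whether transcript length accounts for the lower basement membrane and dedifferentiated lists was not tested. Without Top 5 positive replicate 2, only libraries that stood apart were left in the group, so the count of that fit may carry the same bias. The count was 1200 (744 higher, 456 lower) without Top 5 positive replicate 2, 8 and 9 without replicates 1 and 3, 6, 8 and 14 without the Parental positive replicates. It was 0 with only the compared groups in the fit and 73 with DESeq2. Without the 6 libraries only Top 5 positive replicate 2 was left in its group, so no conclusion is drawn from the count of that fit. PGM5, FBXL7 and FOXP1 kept the call whichever library was left out, unlike the other named genes of this comparison.

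When negative cells were sorted first and then migrated for 4 rounds, FOXP1 rose from 4.54 ± 1.15 CPM in Parental negative to 25.6 ± 8.42 CPM (edgeR adjusted p = 0.000209), PGM5 rose 5.89-fold (edgeR adjusted p = 0.00881) and SMOC1, a matricellular protein, 5.90-fold. TM4SF18 and CALB1, the calcium buffer calbindin, rose 9.64- and 10.8-fold. SORCS1 fell from 50.9 ± 30.7 to 1.64 ± 0.56 CPM (edgeR adjusted p = 0.000868). XYLT1, a proteoglycan xylosyltransferase, fell from 27.7 ± 13.2 to 1.84 ± 0.70 CPM (edgeR adjusted p = 0.00146) and FREM1 from 11.02 ± 2.23 to 0.70 ± 0.52 CPM (edgeR adjusted p = 0.00395). SOX8, GRM8, ITGA9, PCSK1, ATP10B and the mesenchymal factor SNAI2 fell with log2 fold changes of -5.37, -4.31, -3.90, -3.90, -3.47 and -3.77. VCX2 and VCX (9.91- and 8.72-fold higher) are uncertain because of near-identical copies. RMRP was 18.1-fold higher, at 6.87 ± 9.62 against 0.37 ± 0.15 CPM, and its spread came from 1 library, replicate 2, which stood apart from the rest. In all, edgeR called 308 genes, 139 higher and 169 lower. The count was 59 and 127 without Parental negative replicates 1 and 2, 496 and 189 without replicates 1 and 2 of the migrated cells. Higher genes outnumbered lower ones without migrated replicate 1 (289 and 207) and replicate 3 (187 and 98). It was 0 with only the compared groups in the fit, 477 with a replicate block and 719 with DESeq2. Of 37 named genes 5 (FOXP1, SORCS1, FREM1, XYLT1 and VCX2) kept the call whichever library was left out, and the other 32 lost it without Parental negative replicate 1. Without that library the log2 fold changes of SOX8, GRM8, ITGA9, PCSK1, ATP10B and SNAI2 were -3.44, -2.75, -2.63, -2.31, -2.59 and -2.55.

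Cell cycle genes were the list with the smallest p there: 52 of 52 G2/M genes were higher (median log2 fold change 0.56, camera adjusted p = 5.81e-11, adjusted p = 0.631 with an estimated correlation), 4 of them over all genes and 9 adjusted over the list alone. NEK2 and KIF20B, a mitotic kinase and a mitotic kinesin, rose 1.84- and 1.95-fold, CKAP2L 1.74-fold and CKS1B 2.79-fold. Parental negative replicate 1, with a low G2/M mean, was in this comparison too. Dedifferentiated genes were higher in 26 of 31 (adjusted p = 0.000628, adjusted p = 0.631 with an estimated correlation), with CAV2 (2.94-fold) and WNT5A, a non-canonical Wnt ligand (1.79-fold), called and 5 adjusted over the list alone. SPRY4, a feedback inhibitor of MAPK signalling, fell from 443 ± 367 to 73.0 ± 24.6 CPM (edgeR adjusted p = 0.021). PFKFB3, a glycolytic regulator, fell from 162 ± 47.3 to 66.8 ± 1.80 CPM (edgeR adjusted p = 0.014), and the melanosomal glycoprotein GPNMB from 160.2 ± 25.2 to 71.5 ± 5.76 CPM (edgeR adjusted p = 0.0392). EPHB3, EPHA3 and NRCAM fell by 1.29, 1.60 and 2.45 on the log2 scale. Of genes called here, 47 higher and 34 lower were shared with the Bottom 10 against Top 10 difference of the negative sort, where 1.32 and 0.648 were expected, and 0 went opposite ways (Fisher's exact test, one-sided, adjusted p = 4.76e-61 and 1.53e-51). Genes are not independent, so these p-values overstate the evidence.

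Between positive cells sorted first and migrated for 5 rounds and Parental positive cells, edgeR called 6 genes, 1 higher and 5 lower. PXDN rose from 5.89 ± 0.72 to 25.6 ± 7.99 CPM (edgeR adjusted p = 0.0302). SOX11 fell from 36.3 ± 14.4 to 11.96 ± 2.21 CPM (edgeR adjusted p = 0.0388), and LPL, the lipoprotein lipase, from 12.6 ± 7.26 to 3.32 ± 0.76 CPM (edgeR adjusted p = 0.0237). SORCS1 and TMEM178B fell with log2 fold changes of -3.87 and -3.93. The 5 lower genes were also lower in the negative sort after 4 rounds, where 0.0549 would be expected of independent comparisons. The migrated libraries of both sorts with the same replicate number resembled each other, so these were not independent. Dedifferentiated genes were higher in 27 of 31 (camera adjusted p = 0.00181, adjusted p = 0.775 with an estimated correlation), and adjusted over the list alone 0 were called. The count was 3 and 0 without Parental positive replicates 1 and 3, and 0, 1 and 0 without the 3 migrated replicates, 0 with only the compared groups in the fit, 3 without the 6 libraries and 24 with DESeq2. Each of the 5 named genes lost its call in some of these fits (PXDN in 6 of 6, adjusted p up to 0.441). The sorts had 4 and 5 rounds, so their difference mixes sort and rounds. As an interaction it called 0 genes in edgeR, with 555 at an unadjusted p under 0.05 (769 expected by chance) and 5 in DESeq2.

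Genes of chromosome 13 were lower as a group in cells that crossed in 10 rounds. Against the median of all genes, the median log2 fold change of 275 genes between Bottom 10 and Top 10 cells was -0.22 in the negative and -0.44 in the positive sort, and against parental cells -0.22 and -0.36. Chromosome 20 was lower after fewer rounds, with a median over 408 genes of -0.26 in the negative sort migrated 4 rounds, -0.25 in Bottom 5 negative and -0.14 in the positive sort migrated 5 rounds. Each of these 7 medians lay below all of 10000 random sets of the same size and expression. That position was common, since of all 299 medians (23 chromosomes in 13 comparisons) 19 others lay below all random sets and 26 above. Without chromosomes 13 and 20, the largest median in size was 0.114. Chromosome 13 was lower in Bottom 5 negative cells too, by -0.109 (0.03% of random sets as low), and in the positive against the negative sort of Bottom 10 cells, by -0.174. In single libraries the chromosome 13 median, relative to all 30, ran from -0.34 to -0.23 in Bottom 10 positive and from -0.18 to -0.09 in Bottom 10 negative cells, while Top 10 libraries lay at 0.04 or above. The chromosome 20 median ran from -0.24 to -0.18 in the negative sort migrated 4 rounds and stood at 0.06 ± 0.02 in Bottom 10 negative cells.

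**Figure D4:**
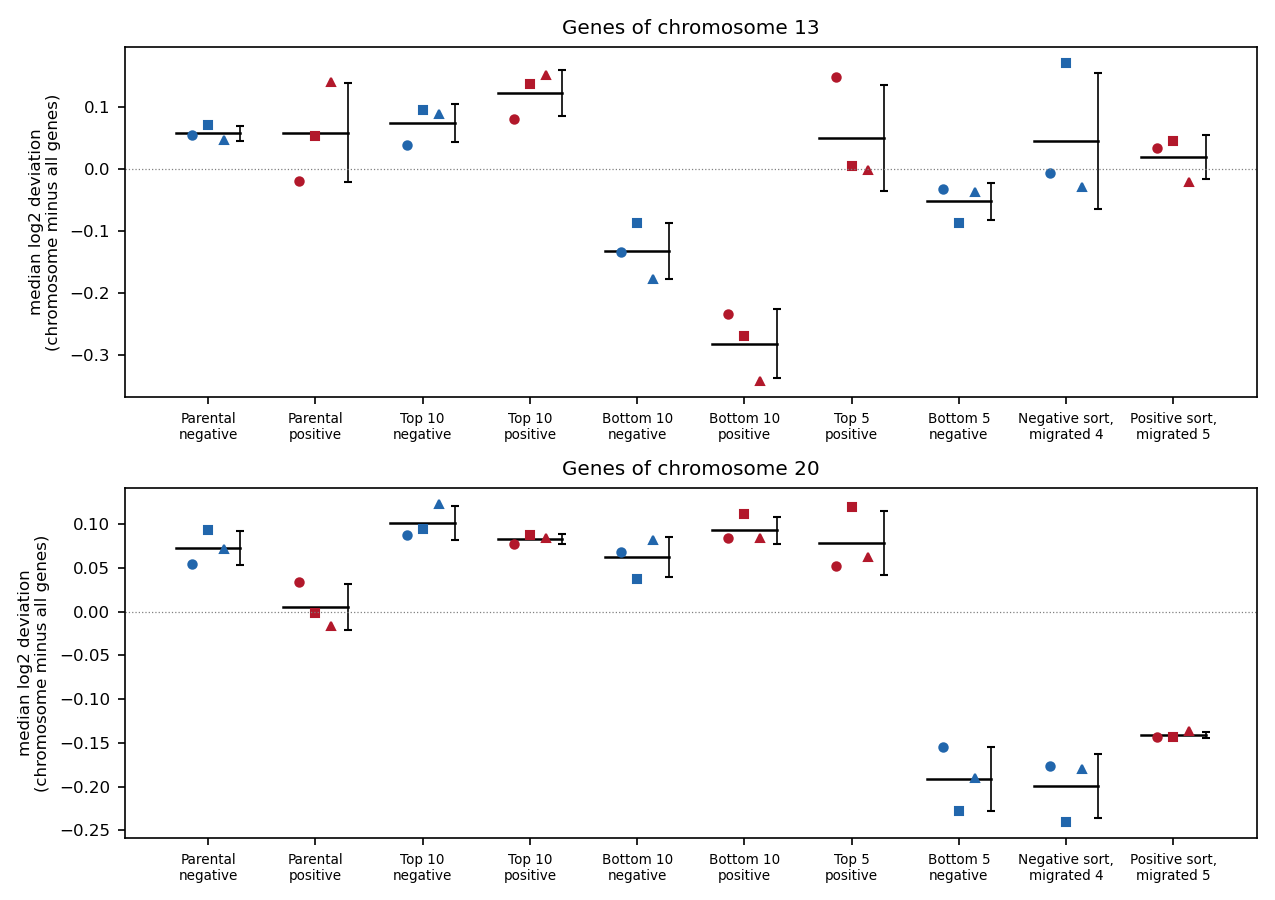
Median log2 level of chromosome 13 and chromosome 20 genes relative to all genes and to the mean of the 30 libraries, in each library by group; blue is the negative and red the positive sort, symbols are replicates 1, 2 and 3, bars are group means and error bars SD. Chromosome 13 is lowest in Bottom 10 positive (-0.28 ± 0.06) and chromosome 20 in the negative sort migrated 4 rounds (-0.20 ± 0.04).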

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

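Chosen only after the result was seen were the tests of copy number on chromosome 20, of the number of chromosomes with shared genes, of the score in migrated cells, of its correlation with ITGB4, of transcript length and of depth, and the counts over other splits of the libraries.

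In cells that crossed in 10 rounds, chromosome 13 genes were lower, and after 4 or 5 rounds chromosome 20 genes were. A trend with GC content and transcript length is argued against as the whole cause, since the shift of chromosome 13 in the positive sort was -0.44 before and -0.403 after a loess fit on both, and that of chromosome 20 after 4 rounds was -0.26 and -0.186. The 6 libraries that stood apart are argued against as well, because without them the shifts were -0.429 and -0.265. A lower copy number in part of the cells predicts a shift along the whole chromosome, and with each chromosome divided by position into 4 equal sets of genes the highest median was -0.18 on chromosome 13 (8 medians, both sorts) and -0.111 on chromosome 20 (12 medians, 3 comparisons). Loss of a copy, in part or all of the cells, is therefore a candidate explanation, untested at the level of DNA. These medians do not tell what share of the cells it would involve.

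Of the 9 genes called between the parental sorts, 6 were called in the same direction between Bottom 10 and Top 10 cells, 5 in the negative and 6 in the positive sort. The 6 libraries that stood apart are argued against, because 16 genes were shared by the parental sort and the negative sort of 10 rounds without them. Gain or loss of 1 chromosome that acts only on its own genes is argued against, because the 6 shared genes lie on 5 chromosomes. An effect of such a change on genes of other chromosomes was not tested. A kind of cell that the sort also separates, with a different share in cells that crossed and cells that did not, may account for the pattern. In groups not used to choose the genes, the lowest score of 9 libraries that crossed lay 4.05 above the highest of 3 that did not. These were 3 groups against 1, so that chance alone puts that group lowest with a probability of 0.25. The test cannot tell a rise in cells that crossed from a fall in those that did not. In the positive sort the score was 0.10 ± 0.56 in parental, 0.29 ± 0.66 in Bottom 10 and -4.64 ± 0.29 in Top 10 cells. In the negative sort it was -3.86 ± 0.44, -1.51 ± 0.455 and -6.23 ± 0.07. The genes were chosen for differences between these same groups, so these scores cannot show where the change lay. Whether the genes called after 10 rounds follow the sort as a whole stays open. Of the 205 of the negative sort 196 went the same way in the parental sort, and of the 145 of the positive sort 135. The signed median of the 205 was 0.881 in edgeR fold changes and 0.895 in differences of mean log2 CPM. On the latter measure the highest of the other splits of the parental libraries gave 0.644, and 10 splits are too few for a share under 0.05. A link of the score with ITGB4 within groups stays open too. Pearson r was 0.710 over 30 libraries with group means removed (0.651 without the 2 farthest, Spearman rho 0.658). With the 216 orders that keep paired groups together, the permutation p of r was 0.0278 and adjusted p = 0.0833 over 3 relations. Selection of such cells and a change within cells during migration cannot be separated by these libraries and were not tested against each other.

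On the second principal component 6 libraries stood apart: Top 10 negative 1, Bottom 10 positive 3, Bottom 5 negative 2, Top 5 positive 1 and 3, and replicate 2 of the negative sort migrated 4 rounds. Lower depth is argued against, because 2 of them had more gene counts than the median of the others, and so is GC content, because the smallest correlation with it in size among the 6 was -0.00061. A bias against long transcripts may set them apart, since their deviation from the other libraries fell with transcript length, with a rho across genes from -0.506 to -0.3005, against -0.193 to 0.264 in 23 of the other libraries (Top 5 positive 2 had no library of its group left to compare, and genes are not independent replicates). No biological explanation was tested.

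Each count of called genes was compared with other splits of the same libraries, which are too few for a share under 0.05: 10 splits for 3 against 3, 20 drawn for an interaction and 4 for paired libraries. In 12 of the comparisons of 3 against 3, 1 split of 10, the real one, reached the real count, and in the sort of Bottom 10 cells 10 of 10 did, with a real count of 0. Real counts were 9, 2, 205, 145, 50, 59, 308, 6, 132 and 25 with 0 as the highest of the other splits, and 38 and 7 (Bottom 10 positive and Top 10 negative against parental cells) with 1. For the interactions, real counts were 0 and the highest others 3, 0 and 7, so that 20 of 20 draws reached them. With the replicate block, real counts were 35, 121, 1355, 1130 and 542, the highest other was 0 and 1 of 4 splits reached them. Of the 205 and 145 genes called after 10 rounds, the signed median in the real parental split, here from differences of mean log2 CPM, was 0.895 and 0.863, and the highest other was 0.644 and 0.642.

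Some gene lists differed between the sorts in how they changed, by a test of the difference itself with camera at a preset correlation. In the change from Top 10 to Bottom 10 cells, positive minus negative sort, cohesin and condensin (adjusted p = 0.00143), G2/M (adjusted p = 0.00143) and YAP and TEAD genes (adjusted p = 0.022) were lower, with adjusted p = 0.838 for each with an estimated correlation. In the sort difference of Bottom 10 cells minus that of parental cells, G2/M (adjusted p = 8.98e-19, 51 of 52 genes lower), S phase (2.86e-08), cohesin and condensin (2.69e-07), dedifferentiated (0.0201), nuclear envelope (0.0267), heterochromatin (0.0465) and fibroblast genes (0.0329) were lower, and antigen presentation (0.00346) and unfolded protein genes (0.0005) higher, with adjusted p from 0.415 to 0.677 with an estimated correlation. In the change on migration after the sort, positive minus negative, G2/M (adjusted p = 2.99e-13), S phase (1.89e-05), cohesin and condensin (0.011) and cancer-testis genes (0.011) were lower and neural genes (0.0226) higher, with adjusted p = 0.816 with an estimated correlation. Parental negative replicate 1, with a low G2/M mean, was in both differences that involve parental cells.

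The share of reads matching more than 1 place, which the comparisons do not use, was above the highest parental library (8.87%) in 9 libraries. It was 9.16% in Top 10 negative 1, 9.20 and 9.32% in Bottom 10 positive 2 and 3, 12.6% in replicate 2 of the negative sort migrated 4 rounds and 8.90% in replicate 3 of the positive sort migrated 5 rounds. It was 9.21 and 10.02% in Bottom 5 negative 1 and 2, and 13.3 and 9.68% in Top 5 positive 1 and 3. All 6 libraries that stood apart on the second principal component were among these 9.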

How the results depend on the processing

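The fits with a replicate block in the groups that pair and without the 6 libraries that stood apart, and the tests on them, were chosen only after the result was seen. Counts of called genes are given for the sort in parental, Top 10 and Bottom 10 cells, for Bottom 10 against Top 10 cells (negative, then positive sort), for Bottom 10 and for Top 10 against parental cells, for the sort followed by 4 or 5 rounds, for Bottom 5 negative and Top 5 positive cells and for the 3 interactions. With RLE factors all 16 counts stayed within 1.5 times, and no alternative turned the direction of a named gene.

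The replicate block in all groups moved 4 of 16 counts, to 27 (parental sort), 98 (Top 10 positive against parental), 477 (4 rounds) and 220 (Bottom 5). Restricted to the groups that pair, it gave 35 and 121 for the sort in Top 10 and Bottom 10 cells, 1355 and 1130 for Bottom 10 against Top 10, and 542 for Bottom 5 negative cells. The cause was not tested. Without 1 replicate number, these paired counts ran from 0 to 55, 0 to 35, 116 to 1932, 92 to 840 and 81 to 1489. No filter on low counts moved 3 counts, to 1 (Top 10 sort), 33 and 4 (Bottom 10 and Top 10 negative against parental).

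DESeq2 called more genes in 15 of 16 comparisons: 75, 5 and 5 for the sorts, 383 and 280 for Bottom 10 against Top 10, 169 and 113 for Bottom 10 and 48 and 210 for Top 10 against parental, 719 and 24 after the sort, 314 and 73 after 5 rounds, and 2 and 5 for the last 2 interactions. The cause was not tested. With only the compared groups in the fit, and so fewer libraries to estimate the spread, 11 counts fell by over 1.5 times and that for Bottom 10 against Top 10 negative by less, to 157: to 1 and 0 for the parental and Top 10 sorts, 31 for Bottom 10 against Top 10 positive, 13 for Top 10 positive against parental, and 0 for the other comparisons with parental cells. The fit without the 6 libraries left only Top 5 positive replicate 2 in its group, so no conclusion is drawn from the Top 5 count below. Without the 6 libraries 10 counts moved, to 25, 0 and 1 for the sorts, 111 for Bottom 10 negative and 0 and 108 for Top 10 against parental, 3 for the positive sort after 5 rounds, 76 and 7 for Bottom 5 and Top 5, and 2 for the last interaction. The cause was not tested.

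Leaving out 1 library at a time, the counts ran from 3 to 18, 0 to 1 and 0 to 1 for the sorts, 91 to 157 and 53 to 113 for Bottom 10 against Top 10, 5 to 39 and 11 to 18 for Bottom 10 and 0 to 26 and 20 to 101 for Top 10 against parental, 59 to 496 and 0 to 5 after the sort, 29 to 124 and 6 to 1200 for Bottom 5 and Top 5, and 0 to 1, 0 to 0 and 0 to 1 for the interactions. Genes shared with the parental sort were 13 and 15 with a replicate block and 42 and 38 with DESeq2 for Bottom 10 against Top 10, 1 and 3 for the Top 10 sort, and 1 with DESeq2 for the Bottom 10 sort. DESeq2 gave 147 shared genes for the migration differences of both sorts, 23 for the sorts followed by migration, and 161 (126 with a replicate block) and 14 for these against the 10-round differences. The cause was not tested.

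For gene lists, the estimated correlation ended 134 of 134 calls, the replicate block 4 of 134 and the fit without the 6 libraries 35, and there semaphorin and ephrin genes in Top 5 positive cells turned direction (adjusted p = 0.555). The fit without the 6 libraries left only Top 5 positive replicate 2 in its group, so no conclusion is drawn from that turn. In the fit with paired libraries 33 of 37 calls held, and 1 with an estimated correlation.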

Other observations

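The values in this part come from the fit with a replicate block in the Top 10 and Bottom 10 groups, which was chosen only after the result was seen, and these genes were chosen after their values were seen. Of 20 melanocyte lineage genes, 6 were called lower in Bottom 10 than in Top 10 cells of the positive sort and 14 were not called (camera adjusted p = 0.0576 for the list, and 0.301 with an estimated correlation). In the negative sort 4 of them were called lower and DCT higher (adjusted p = 0.0111, and 0.154 with an estimated correlation). Among the 6, OCA2, a melanosomal transporter, had a log2 fold change of -2.13 ± 0.48 (edgeR adjusted p = 0.0242), the endothelin receptor EDNRB -1.66 ± 0.10 (edgeR adjusted p = 4.16e-05) and MITF -0.65 ± 0.14 (edgeR adjusted p = 0.0177). TFAP2B, a neural crest factor, was lower in both sorts, with -3.01 ± 0.18 in the negative and -3.62 ± 0.19 in the positive sort (edgeR adjusted p = 2.36e-05 and 1.29e-05). NGFR, the low-affinity nerve growth factor receptor, was higher, with 2.45 ± 0.48 and 1.87 ± 0.46 (edgeR adjusted p = 0.0106 and 0.0352), and so was the receptor kinase AXL, with 1.15 ± 0.17 and 1.04 ± 0.17 (edgeR adjusted p = 0.00239 and 0.00455). The mesenchymal factor SNAI2 was lower in both sorts (-2.18 ± 0.20 and -1.67 ± 0.26), while TWIST2 was higher (1.54 ± 0.22 and 1.42 ± 0.21, edgeR adjusted p up to 0.00389 for these 4 values). Each of these values rests on 3 pairs.

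Chemokines CXCL8 and CXCL1 were higher in Bottom 10 cells of both sorts, with log2 fold changes of 2.46 ± 0.20 and 2.14 ± 0.23 in the negative sort and 2.21 ± 0.20 and 2.05 ± 0.23 in the positive sort (edgeR adjusted p up to 0.000659). Guidance genes SEMA3A, NRP1 and EPHA2 had log2 fold changes of 1.12, 1.27 and 1.55 in the negative sort (edgeR adjusted p up to 0.00566), where 13 genes of that list were called higher and 5 lower. The antigen-presenting HLA-B and HLA-C were lower in the negative sort (-1.06 ± 0.17 and -0.92 ± 0.15, edgeR adjusted p = 0.00364 and 0.00402), whereas in the positive sort they stood at -0.12 and -0.07 (edgeR adjusted p = 0.671 and 0.777). The interaction in that fit called 0 genes in edgeR, with 1905 at an unadjusted p under 0.05, so no single gene was shown to differ between the sorts. As a list, antigen presentation genes were higher in it, positive minus negative sort (camera adjusted p = 0.00576 with a preset correlation). Cohesin and condensin, heterochromatin, S-phase, G2/M and fibroblast genes were lower. None of these list calls held with an estimated correlation. DESeq2 was not run on this fit.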
